A study of Dugesia japonica with 18 samples.

How the data were processed

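Whole-body RNA of the planarian Dugesia japonica was measured by 3' mRNA sequencing (Lasy-Seq, in which each RNA sample gets its own index at reverse transcription and the samples are then pooled into a single library preparation). Per the labels' protocols, animals of about 5 mm from the clonal strain SSP were starved, irradiated with X-rays at 150 Roentgens and lysed at the sampling time. The 18 libraries fall into 6 groups of 3: unirradiated animals (day 0) and animals at days 0.5, 1, 3, 5 and 7 after irradiation. The series' design text states that day 0 was not irradiated and does not list day 0.5, whereas the treatment protocol in the labels gives the same dose for all samples without an exception for day 0. Groups and replicate numbers came from the sample titles, and the sampling day in the deposited sample table was the same for all 18 libraries. The series describes the replicates as biological. The number of animals per library is not given in the sources used here.

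The deposited table holds estimated counts of reads per gene model, not normalized, with 1 column per library. The submitters' processing notes name fastp 0.21.0, BWA 0.7.17-r1188 and Salmon, without a role or order. The version of Salmon, the reference sequences and the gene models are not given in the sources used here. Per the file headers, a second deposited table gives the total count and the number of rows above 0 for each library. In all 18 libraries, the number of rows above 0 was the same as that computed from the count table. The totals differed from the computed ones by less than 1 count. The count table has 25658 rows, of which 92 are ERCC control RNAs and 25566 are gene models with IDs of the form DjGI, number, hyphen, number. The ERCC rows took 0.004% of all counts and were left out of library sizes and tests. As printed in the table, with no tolerance, 38 values in 34 gene models were not whole numbers, and these were rounded. The 25566 IDs carry 19543 different first numbers. Some IDs that share a first number have nearly equal counts, so reads of near-identical copies may have been divided between them.

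The files do not pair the IDs with gene names, and no annotation or genome was used here. The 18 gene lists fixed before the data were examined (stem cell, cell cycle, epidermal progeny, muscle, neuron, intestine, DNA repair and others) therefore could not be matched and were not tested. The rule for named genes, fixed at the same time, then allowed 4 IDs: the gene model that rose most and the one that fell most at day 0.5 and at day 7, among those past the threshold, with a mean of at least 20 CPM (counts scaled to a common library size) in the higher group and no overlap between the libraries of the groups compared.

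Gene models with low counts were removed with the default filter of edgeR by group (a minimum count of 10 and a minimum total of 15), which left 17129. Counts were scaled by the trimmed mean of M values (TMM), with factors from 0.94 to 1.13. The quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 was fitted over all 18 libraries with 1 mean per group. Each day was compared with day 0, and each day with the sampling day before it. A joint test asked whether a gene model differed from day 0 at any day. All tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 for the adjusted p. The standard error of a log2 fold change was taken as its size divided by the square root of its F value. This is an approximation, and it can be too small for large falls to few counts. The biological coefficient of variation was 0.107. CPM in the text are scaled with TMM.

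These steps and the alternatives below were fixed before the data were examined. The alternatives were DESeq2 1.42.0, RLE size factors, upper-quartile scaling, library totals, no filter beyond 1 read, a filter of at least 30 reads in 3 libraries, removal of the 10 most abundant gene models, thinning of each library to 4679195 counts, the replicate number as a block, only the 6 libraries compared, an added 2-fold limit, and leaving out each library in turn. Chosen after seeing the data were scaling by the ERCC counts, summing counts over IDs with the same first number, the early and late sets of falling genes, and the counts of early changes that turned back. The early and late sets were taken from gene models that passed the test at day 7, had fallen at least 4-fold and averaged at least 20 CPM at day 0. The early set had reached at least 50% of its day 7 log2 fall at day 1, and the late set less than that.

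The fit was tested on simulated data for day 7 against day 0, over 16685 gene models drawn from the day 0 means, with 100 gene models changed 1.5-fold and 100 changed 3-fold. It recovered 52% of the 1.5-fold and 100% of the 3-fold changes, and 3.8% of its calls were false. The changes were set only in gene models above a minimum level at day 0, so recovery at low counts was not measured. Few gene models were changed in the simulation, while 41.6% of those tested were called at day 7 in the data. The 3.8% therefore does not measure false calls in the data. Of 50 simulated early and 50 simulated late genes, 49 and 46 were placed in their own set. The early ones were given their full fall at day 1 and the late ones none. These numbers therefore do not measure the placement of genes near the 50% cut. Libraries of the same group differed by more than counting noise in all pairs, with a chi-square per degree of freedom from 3.05 to 9.14 over gene models with at least 20 counts in the pair. No library therefore looked like a second deposit of another in its group, and libraries of different groups were not compared in this way. Same-numbered libraries showed little sign of deviating from their group means together: of 45 such pairs, 3 had a correlation above 0.1, and the highest was 0.12. The median was -0.001, against 0.005 for pairs with different numbers. A weak pairing is not excluded. The numbers were therefore not used to pair libraries. Library totals ran from 4679195 to 12605652 counts. The reads carry no stated molecular identifiers, so intervals from counts cover counting error only.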

Results

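Planarians are flatworms that keep dividing stem cells, called neoblasts, throughout the body, and X-rays remove dividing cells. The series followed the transcriptome of whole animals over a week after X-irradiation. Messenger RNA was counted by 3' sequencing in 18 libraries, with 3 biological replicates at day 0 (not irradiated, per the series' design text) and at days 0.5, 1, 3, 5 and 7. No unirradiated animals were sampled at days 0.5 to 7. Effects of irradiation therefore cannot be told apart from those of elapsed time in any comparison with day 0. Day 0 libraries averaged 10687272 ± 2575226 counts (SD, n = 3), and the averages were 9662883 ± 2190791 at day 0.5, 9304693 ± 413958 at day 1, 8787153 ± 746916 at day 3, 6665657 ± 737955 at day 5 and 5415712 ± 718228 at day 7. The exact two-sided permutation test against day 0 gave p = 0.1 at days 5 and 7, the smallest value that 3 against 3 libraries allow (adjusted p = 0.25 over 5 comparisons). Between 20515 and 22192 gene models had at least 1 count in a library. The 10 most abundant gene models took from 18% to 21.8% of the counts.

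The libraries were ordered by day on the first principal component of log2 CPM, which held 40.4% of the variance. Its mean was -57.1 ± 2.7 at day 0, -27.6 ± 3.4 at day 0.5, -11.9 ± 1.2 at day 1, 14.8 ± 3.1 at day 3, 32.7 ± 1.4 at day 5 and 49.2 ± 5.2 at day 7 (SD, n = 3 each). The second component, with 10.4%, was high at day 0 (22.4 ± 1.2) and day 7 (25.3 ± 7.9) and low at day 1 (-20.2 ± 2.7) and day 3 (-20 ± 2.6).

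**Figure D1:**
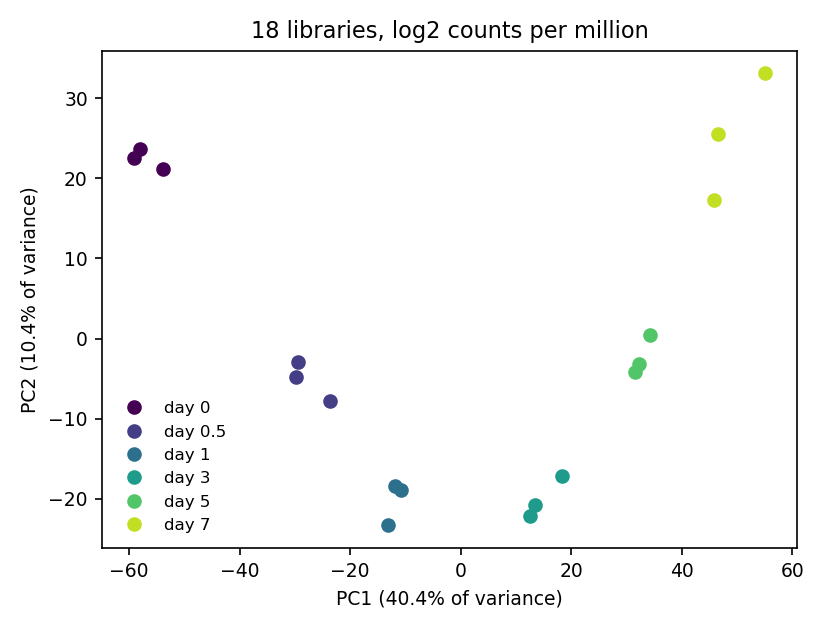
First and second principal components of log2 CPM for the 18 libraries, 1 point per library, coloured by day after irradiation. The 3 libraries of each day lie together, and the days follow in order along the first component from day 0 at -57.1 to day 7 at 49.2.

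The first comparisons asked what changed within the first day. At day 0.5, 1718 of 17129 gene models differed from day 0 (edgeR quasi-likelihood test, adjusted p below 0.05). Of these, 1275 fell and 443 rose. The falls were larger: 320 gene models fell and 18 rose at least 2-fold, and 74 fell and 3 rose at least 4-fold. The median log2 change was -0.69 among those that fell and 0.4 among those that rose. At day 1 the number had grown to 3422, with 2193 lower and 1229 higher than at day 0, of which 689 had fallen and 54 had risen at least 2-fold.

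The gene model that rose most at day 0.5 was DjGI016614-001. It went from 5.51 ± 1.29 CPM at day 0 to 28.9 ± 1.24 CPM at day 0.5 (SD, n = 3 each). That is a log2 change of 2.43 ± 0.16 (SE; edgeR adjusted p = 2.03e-11). It stayed at 28 ± 4.02 CPM at day 1 and was still higher than day 0 at day 3, with a log2 change of 1.68 ± 0.16 (SE; edgeR adjusted p = 3.84e-09). Its level was 12.7 ± 2.16 CPM at day 5 and 10.3 ± 0.42 CPM at day 7, the last of these with a log2 change of 0.94 ± 0.18 (SE; edgeR adjusted p = 0.000138).

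Among gene models that met the rule for named genes (at least 20 CPM in the higher group, no overlap), DjGI012618-001 fell most at day 0.5. It dropped from 33.4 ± 1.71 CPM at day 0 to 4.49 ± 1.26 CPM at day 0.5 (SD, n = 3 each), a log2 change of -2.87 ± 0.2 (SE; edgeR adjusted p = 5.47e-11). Its level was 2.05 ± 0.632 CPM at day 1, 1.19 ± 0.218 CPM at day 3, 0.565 ± 0.237 CPM at day 5 and 0.397 ± 0.379 CPM at day 7. The day 7 libraries held between 0 and 4 counts of it, so its day 7 log2 change of -6.28 ± 0.33 (SE; edgeR adjusted p = 4.63e-15) rests on few reads. That SE is likely too small, since the SE of its step from day 5 to day 7 was 0.68. The files do not name either gene.

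The day 0.5 count depended on single libraries. It was 876 without day 0 replicate 1 (685 fell, 191 rose), 934 without day 0.5 replicate 2 (694 fell, 240 rose) and 1111 without day 0.5 replicate 3 (222 rose). The rises numbered 253 and 259 without day 0 replicates 2 and 3, 67 with scaling by the ERCC controls and 689 with upper-quartile scaling, while 814 fell with ERCC scaling. At day 1 the 1229 rises became 755 and 810 without day 0 replicates 1 and 2, 717 without day 1 replicate 2, 602 with ERCC scaling and 1910 with upper-quartile scaling. The share of calls that fell was 74.2% at day 0.5 and 64.1% at day 1. It was 60.9% and 51% with upper-quartile scaling, and it was 92.4% at day 0.5 with scaling by the ERCC controls.

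The later comparisons asked how far the change went over the week. At day 3, 5452 gene models differed from day 0 (3175 lower, 2277 higher). At day 5 there were 6111 (3576 lower, 2535 higher), and at day 7 there were 7125 (3968 lower, 3157 higher), or 41.6% of those tested by edgeR. Large falls outnumbered large rises at each of these days. At day 3, 1278 gene models had fallen and 71 had risen at least 2-fold, at day 5 the numbers were 1588 and 143, and at day 7 they were 1870 and 561. At day 7, 161 gene models were at least 16-fold lower than at day 0, against 1 at day 0.5.

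Over all calls the balance was closer, and it depended on the scaling. At day 7, 55.7% of the calls were falls with TMM, 48% with library totals and 46.2% with upper-quartile scaling. The last of these moved the median log2 change of all gene models to 0.12, against 0.02 with TMM. At day 5 the share was 58.5% with TMM and 49.5% with library totals.

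**Figure D2:**
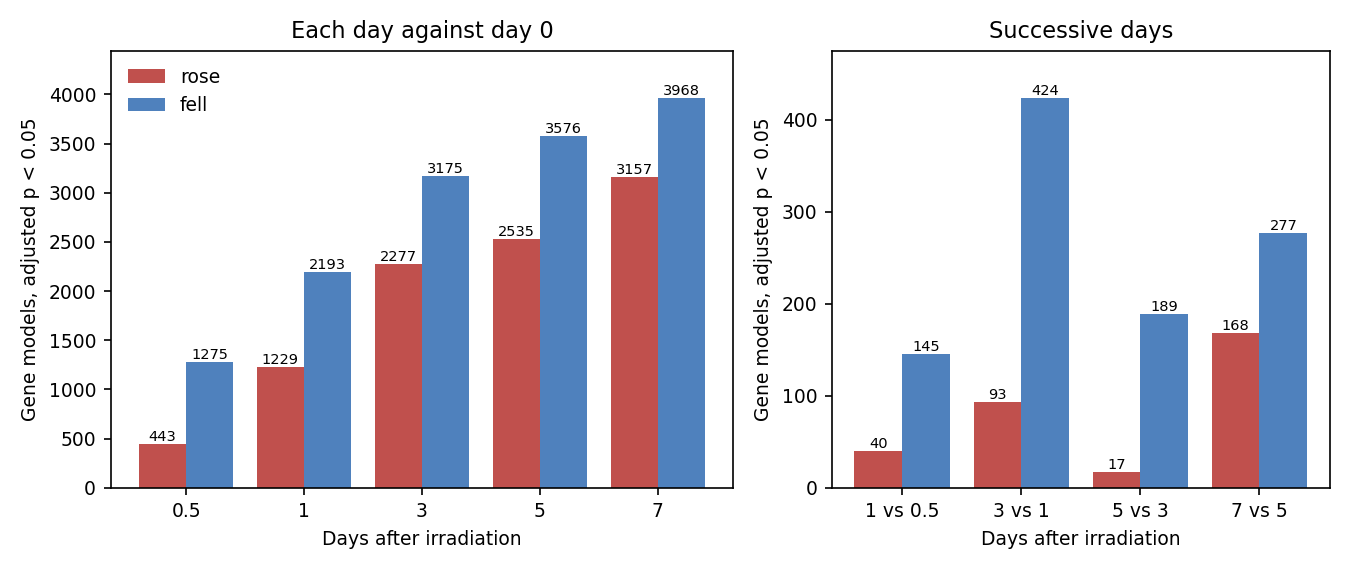
Number of gene models that rose (red) or fell (blue) with an edgeR adjusted p below 0.05, for each day against day 0 (left) and for each day against the sampling day before it (right). Calls against day 0 grew from 1718 at day 0.5 to 7125 at day 7, and falls outnumbered rises in each comparison with TMM scaling.

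Among gene models that met the rule for named genes (at least 20 CPM in the higher group, no overlap), DjGI000021-009 rose most at day 7. It stood at 3.98 ± 2.55 CPM at day 0, 9.82 ± 2.51 CPM at day 5 and 29.5 ± 6.34 CPM at day 7 (SD, n = 3 each). Its log2 change at day 7 was 2.86 ± 0.31 (SE; edgeR adjusted p = 1.35e-08). At days 0.5, 1 and 3 it was not called, with log2 changes of 0.93, 0.76 and 0.62. Its ID shares the first number with 9 others, and reads may have been divided between them, so its level is uncertain. Without day 0 replicate 1 the log2 change at day 7 was 2.43, and without day 0 replicate 2 it was 3.56.

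Among gene models that met the rule for named genes (at least 20 CPM in the higher group, no overlap), DjGI019169-001 fell most at day 7. Its levels at days 0, 0.5 and 1 were 49.1 ± 14.5, 42.5 ± 13.7 and 31.5 ± 11.5 CPM (SD, n = 3 each), and it was not called at either of the first times. At day 3 it was at 0.511 ± 0.363 CPM, a log2 change of -6.47 ± 0.43 (SE; edgeR adjusted p = 2.25e-12). That SE is likely too small, since the SE of its step from day 3 to day 5 was 1.02. DjGI019169-001 stayed at this level at day 5 (0.508 ± 0.293 CPM) and day 7 (0.552 ± 0.833 CPM). The day 7 libraries held between 0 and 8 counts of it, and its day 7 log2 change of -6.47 became -8.93 without day 7 replicate 1.

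**Figure D3:**
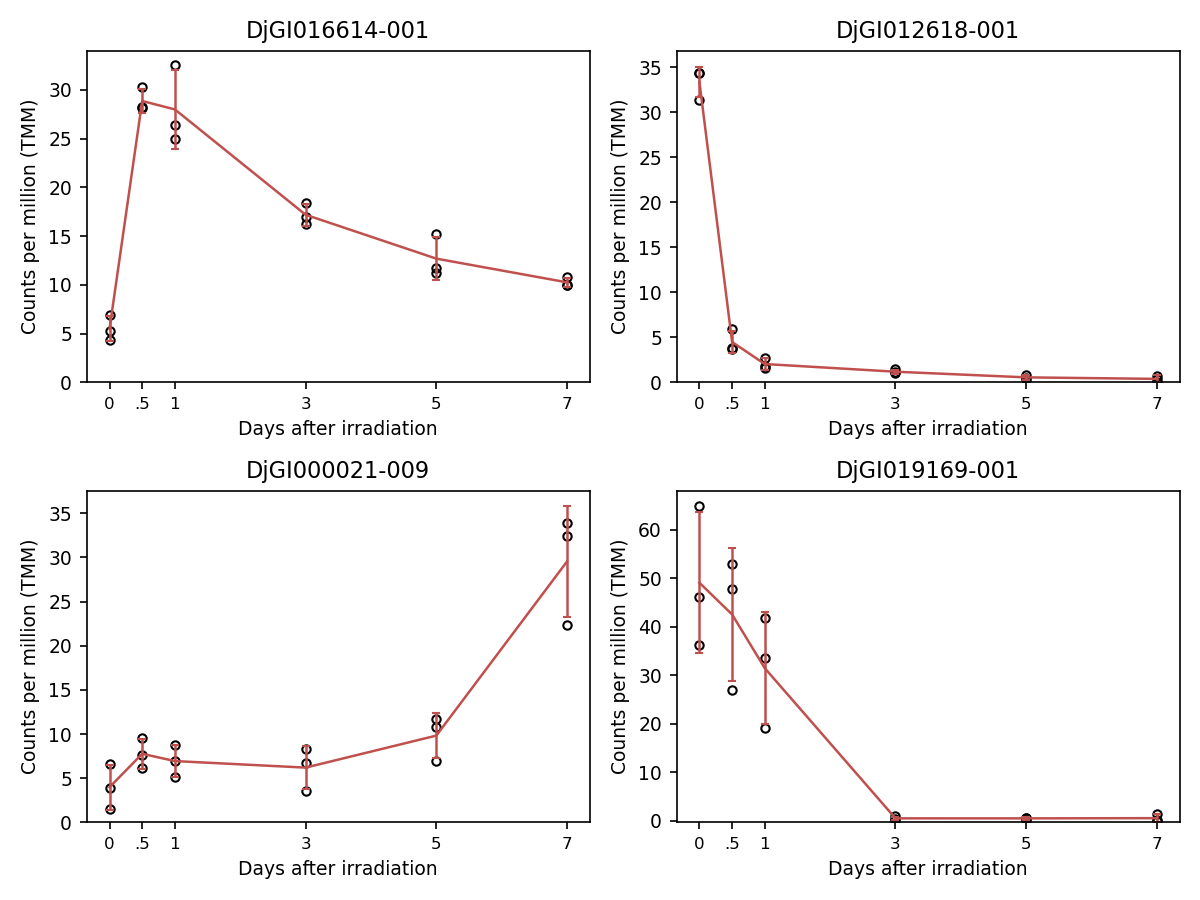
CPM (counts scaled to library size with TMM) of the 4 named gene models against days after irradiation, with 1 open point per library and the mean ± SD (n = 3) in red. DjGI016614-001 peaks at days 0.5 and 1, DjGI012618-001 falls by day 0.5, DjGI000021-009 is highest at day 7 (29.5 CPM), and DjGI019169-001 falls between days 1 and 3.

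Gene models that fell strongly did so at different times. By day 7, 496 gene models had fallen at least 4-fold, and 152 of these had averaged at least 20 CPM at day 0. At day 1, 60 of the 152 had reached at least 50% of their day 7 log2 fall (the early set), and 92 had not (the late set). In steps of 20% of the later fall, 10 gene models were above their day 0 level by 20% to 40% and 46 by up to 20%. Below their day 0 level, 20 had reached up to 20% of the fall, 13 had reached 20% to 40%, 11 had reached 40% to 60%, 39 had reached 60% to 80% and 13 had reached 80% to 100%.

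All 60 members of the early set were lower than day 0 at each of the 5 times by edgeR. Their median log2 change was -1.44 at day 0.5, -2.47 at day 1, -2.85 at day 3, -2.9 at day 5 and -2.99 at day 7. From day 0.5 to day 1, 43 of the 60 fell further, and from day 1 to day 3, 17 did. From day 3 to day 5 and from day 5 to day 7, 1 did in each step. Together they held 1.2 ± 0.043% of the reads at day 0, 0.512 ± 0.059% at day 0.5, 0.325 ± 0.011% at day 1 and 0.187 ± 0.009% at day 7 (SD, n = 3). DjGI012618-001, with its fall by day 0.5, shows this course.

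At day 1, 35 of the 92 members of the late set were higher than at day 0, 24 were lower and 33 did not pass the test. The median log2 change was 0.24 at day 1, -0.61 at day 3, -2.34 at day 5 and -3.48 at day 7. Of the 92, 75 fell from day 1 to day 3, 72 from day 3 to day 5 and 56 from day 5 to day 7, and none rose in these steps. They held 2.7 ± 0.111% of the reads at day 0, 3.21 ± 0.192% at day 1, 1.46 ± 0.068% at day 3, 0.526 ± 0.025% at day 5 and 0.24 ± 0.045% at day 7 (SD, n = 3). DjGI019169-001 belongs to the late set, but it had reached 100% of its day 7 fall at day 3. The members of this set did not follow 1 course. At day 3 the interquartile range of their log2 change was -1.76 to -0.18, and DjGI017686-001 had reached only 12.3% of its fall at day 5. The sets were picked for a low day 7 level and parted by their day 1 level, so neither their fall to day 7 nor the difference between them at day 1 is independent evidence. With DESeq2, 58 of the 60 and 91 of the 92 were placed in the same set.

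**Figure D4:**
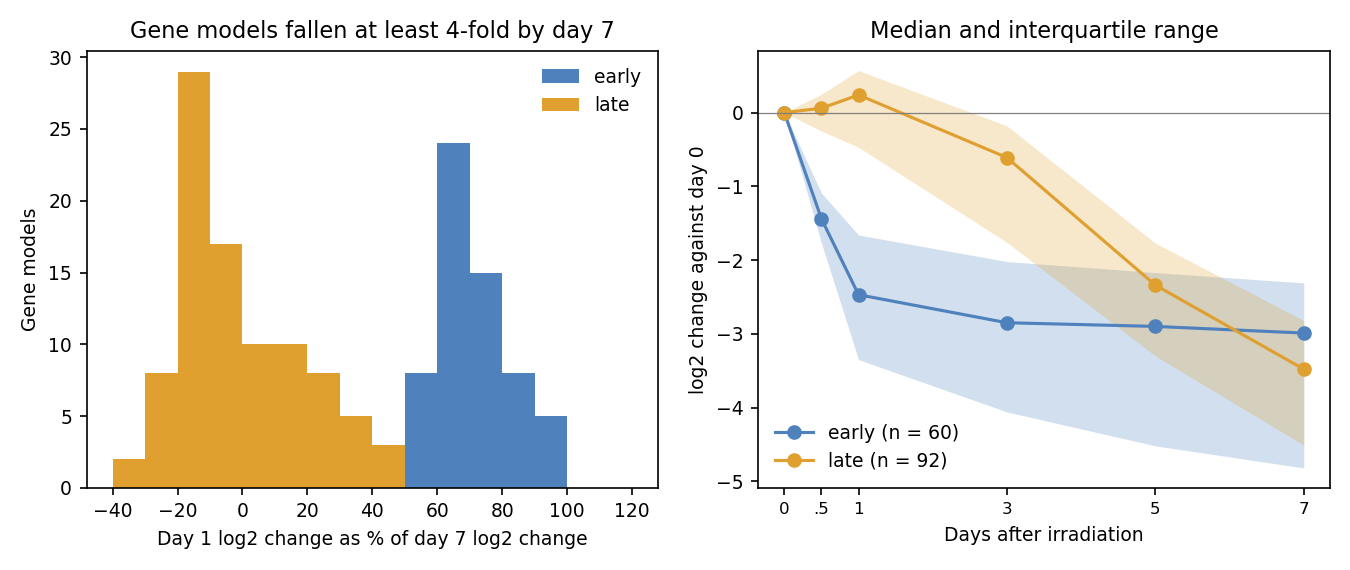
Left, number of gene models by the log2 change at day 1 as a percentage of the log2 change at day 7, for the 152 gene models that fell at least 4-fold. Right, median log2 change against day 0 (lines) with the interquartile range (shading) for the early set (60, blue) and the late set (92, orange). At day 1, the time by which the sets were parted, the early set was at -2.47 and the late set at 0.24.

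Successive days were also compared with each other. These steps contrast groups other than day 0, although the day 0 libraries entered the shared filter and estimate of spread. From day 0.5 to day 1, 185 gene models differed (145 fell, 40 rose). From day 1 to day 3 there were 517 (424 fell, 93 rose), from day 3 to day 5 there were 206 (189 fell, 17 rose) and from day 5 to day 7 there were 445 (277 fell, 168 rose). In the last step 53 gene models rose at least 2-fold, against 3, 5 and 4 in the steps before. At an unadjusted p below 0.05 the numbers were 1786, 2586, 1590 and 2565.

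These step counts changed with single libraries. The day 1 to day 3 count was between 251 and 337 without any one of day 1 replicates 1 and 3 and day 3 replicates 2 and 3, and the day 0.5 to day 1 count was 99 without day 1 replicate 3 and 107 without day 0.5 replicate 3. The day 5 to day 7 count was 272 without day 7 replicate 3, with 51.8% falls against 62.2%, and 276, 280 and 289 without day 5 replicates 3, 1 and 2. The rises moved as well. From day 5 to day 7, 78, 109 and 99 rose without day 5 replicates 1, 2 and 3. From day 1 to day 3, between 22 and 37 rose without any one of the libraries of these days. From day 0.5 to day 1 it was 16 to 26 without any one of replicates 1 and 3 of either day, and from day 3 to day 5 it was 3 to 8 without any day 3 library or day 5 replicate 2 or 3. With only the 6 libraries compared, 229 rose from day 1 to day 3 and 102 from day 5 to day 7, so the order of the steps by their rises was not stable. With ERCC scaling the 4 steps gave 73 falls and 27 rises, 127 and 13, 142 and 4, and 156 and 65. From day 0.5 to day 1, 94 rose with library totals, 72 with no filter on low counts and 26 with thinned libraries. From day 1 to day 3, 166 rose with DESeq2 and 61 with thinned libraries. From day 3 to day 5, 35 rose with library totals and 26 with only the 6 libraries compared, and from day 5 to day 7, 283 rose with no filter. With library totals in place of TMM, 56.1% of the day 0.5 to day 1 calls were falls, against 78.4%.

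In the joint test, 7227 gene models differed from day 0 at some time. Of these, 4120 (57%) had their largest change at day 7, 1547 at day 5, 946 at day 3, 415 at day 1 and 199 at day 0.5. Among gene models that did not pass the joint test, 33.7% had their largest fitted change at day 7.

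Most early falls were still present a week later. Of the 1275 gene models that fell at day 0.5, 1175 (92.2%) were also lower at day 7, against 295 for independent lists of these sizes. Of the 443 that rose at day 0.5, 277 (62.5%) were also higher at day 7, against 82 for independent lists. Unchanged groups simulated against shared day 0 libraries gave 0 joint calls in either direction, as the mean of 20 simulations. No gene model changed in these simulations, so hardly any calls could arise at either time. The 0 therefore does not measure how shared controls raise the overlap of real changes. Across gene models, which are not independent replicates, the log2 changes at days 0.5 and 7 correlated at 0.62, against 0.45 in the simulation. Their covariance was 0.24 against 0.031 in the simulation. A split of the 3 day 0 libraries would leave 1 of the comparisons with a single control library, and none was made for the overlap, so part of the excess may come from the shared controls. The joint calls at days 0.5 and 7 numbered 1452, and 777 without day 0 replicate 1 and 806 without day 0.5 replicate 2. Joint rises numbered 126, 170 and 173 without day 0 replicates 1, 2 and 3, 156 and 143 without day 0.5 replicates 2 and 3, 43 with ERCC scaling and 473 with upper-quartile scaling. Joint falls numbered 651 without day 0 replicate 1, 650 without day 0.5 replicate 2, 767 with ERCC scaling and 993 with upper-quartile scaling.

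Of the gene models that fell at day 5, 3132 (87.6%) were also lower at day 7, against 828 for independent lists. Of those that rose at day 5, 1906 (75.2%) were also higher at day 7, against 467 for independent lists, and 2 gene models were called in opposite directions. The correlation of log2 changes across gene models was 0.88, against 0.42 in the simulation, and the covariance was 0.634 against 0.03. Over all 5 times, 1096 gene models were lower than day 0 at each time and 224 were higher at each time. Calls in both directions at different times were found for 178 gene models.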

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

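The tests of the split into early and late sets and the counts over other groupings of the libraries were chosen after the result was seen, whereas the tests of scaling and of shared reads were written down first.

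Effects at different times were compared with each other in 4 steps, and 185, 517, 206 and 445 gene models differed between days 0.5 and 1, 1 and 3, 3 and 5, and 5 and 7. Leaving out 1 library lowered the first, second and last of these to as few as 99 (day 1 replicate 3), 251 (day 3 replicate 3) and 272 (day 7 replicate 3). Also more than 1.5 times lower were 107 without day 0.5 replicate 3 in the first, values from 277 to 337 without day 1 replicate 3, day 1 replicate 1 and day 3 replicate 2 in the second, and 276, 280 and 289 without day 5 replicates 3, 1 and 2 in the last. With ERCC scaling the 4 counts were 100, 140, 146 and 221, and with only the 6 libraries compared the second was 824 and the last 211. Among the named gene models, DjGI016614-001 changed by -0.7 ± 0.14 on the log2 scale from day 1 to day 3 (edgeR adjusted p = 0.00265). DjGI012618-001 changed by -1.15 ± 0.27 from day 0.5 to day 1 (edgeR adjusted p = 0.0261), and DjGI019169-001 by -5.85 ± 0.45 from day 1 to day 3 (edgeR adjusted p = 3.4e-10). DjGI000021-009 changed by 1.57 ± 0.29 from day 5 to day 7 (edgeR adjusted p = 0.00145). The ± values are standard errors, which can be too small for large falls to few counts.

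The split of the strongly falling gene models into an early and a late set is the pattern most open to follow-up. Over the 152 gene models, 2 normal components of the share reached at day 1 were preferred to 1 by a BIC difference of 76.5, with means of -4% and 67.9%. A single skewed distribution can also favour 2 normal components, so such a difference alone does not show 2 separate groups. Among the 77 gene models with at least 30 counts in each day 7 library, the difference was 48. This argues against low counts at day 7. With day 0 replicate 1 for day 1 and the other day 0 libraries for day 7, the difference was 71. This argues against chance values of the day 0 libraries. With 1 ID per first number the difference was 80.7. That choice kept 143 of the 152 gene models and any reads shared with IDs outside them. It therefore cannot decide whether shared reads play a part. A candidate biological explanation is that the early set is used by the X-ray-sensitive dividing cells and the late set by cells that descend from them and are no longer replaced. It stays untested, because the IDs have no names here and the stem cell and progeny lists could not be matched. The series also holds no unirradiated animals at the later days to set beside these falls.

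At day 1 the median log2 change of the 92 late members was 0.24 with TMM, with 35 called higher and 24 called lower. Members were chosen for a small fall or none at day 1, which raises that median, so it does not show that the set rose. The lowest value over RLE, upper-quartile, library-total and ERCC scaling was also 0.24, with 35 to 40 members higher and 22 to 25 lower. The limit of 0.10 set beforehand for a scaling effect was out of reach, since each of these scalings moved the median of all gene models upward, by 0.01 to 0.06. A scaling error shifts all gene models alike, so it cannot set these members apart from the others. Their median was 0.24 against 0 for all gene models with TMM, and 0.29 against 0.05 with ERCC scaling. Whether they rose against day 0 still cannot be told apart from the scaling and the choice of members.

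IDs that share a first number nearly always changed in the same direction at day 7: 98.1% of 2553 pairs of called IDs in 627 sets did. For the 1803 pairs left after a limit on shared reads, the share was 97.7%, against at most 55.8% in 1000 shuffles over these pairs. The limit, set beforehand, removed pairs whose replicate deviations correlate at 0.5 or more. That limit was wrong: of 934 pairs with totals within 5% of each other, 600 lay below it, so it did not remove pairs that may divide the same reads. Among 274 pairs over 4-fold apart in total, 88.7% changed in the same direction. Shared reads and related genes cannot be told apart here, since the sequences behind the IDs were not used, and no biological explanation was tested.

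Reads of ERCC control RNAs, which the comparisons do not use, amounted to 6068 over the 18 libraries, with 190 to 487 in each, above 3, the upper limit on the expected count where 0 counts are seen. They ran from 33.8 to 47 CPM, relative to the counts of gene models, with group means between 38.23 and 41.87 CPM. The ratio of day 7 to day 0 was 1.05 (exact 95% interval 0.96 to 1.16), while library totals at day 0 were 1.97 times those at day 7. The interval pools the reads of each day and covers counting error only. It leaves out differences between libraries, which ran from 33.8 to 47 CPM within day 5.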

How the results depend on the processing

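ERCC scaling, summed IDs and the early, late and turned-back counts were chosen after seeing the data; the other alternatives were fixed before. Of 438 values under alternatives, 399 stayed within 1.5 times the original count or kept the direction and call, and 0 named gene models reversed. The balance of calls turned to rises at day 7 with upper-quartile scaling (4088 higher, 3509 lower) and library totals (3809 and 3519), at day 5 with library totals (3176 and 3107), and among largest changes at day 7 with both (2343 and 1949, 2215 and 1960). A 2-fold limit gave 338, 743, 1349, 1731 and 2431 gene models for days 0.5, 1, 3, 5 and 7 against day 0, and 66, 96, 96 and 135 for the 4 steps, by its own construction. ERCC scaling gave 881 at day 0.5 and 2094 at day 1 against day 0, 100, 140 and 221 for days 1 against 0.5, 3 against 1 and 7 against 5, 810 joint calls at days 0.5 and 7, and 137 rises and 24 falls that turned back by day 7. The cause was not tested; an ERCC total rests on as few as 190 counts. With only the 6 libraries compared, day 3 against day 1 gave 824 and day 7 against day 5 gave 211, and the cause was not tested. Leaving out 1 library, which leaves fewer libraries to test, gave 876 to 1615, 2463 to 2910, 4503 to 4724, 5164 to 5423 and 6063 to 6656 for the 5 days against day 0, and 99 to 192, 251 to 367, 141 to 171 and 272 to 443 for the 4 steps. It gave 6304 to 7285 for the joint test, 3604 to 4124 with the largest change at day 7, 777 to 1600 joint calls at days 0.5 and 7, 56 to 73 early and 90 to 104 late gene models, and as few as 175 rises and 48 to 91 falls that turned back, the most rises within 1.5 times the original 290. The early and late sets numbered 51 to 77 and 84 to 99 under the 11 others that gave them; the 2-fold limit and the fits of 6 libraries did not. Thinned to 4679195 counts, the libraries gave 1211, 2598, 4439, 5185 and 6195 against day 0, so unequal depth did not set the order of the days. Summed over 13554 first numbers, they gave 1435, 2850, 4611, 5194 and 6006. With the replicate block the counts were 1715, 3415, 5447, 6106 and 7049, and 10 of 18 libraries correlated best with a library of their own number. Each named gene model kept its direction and call under every alternative that included it, with a highest adjusted p of 3.27e-07 in edgeR or DESeq2. Summed IDs give no value for the named gene models, and the gene lists and their alternatives were not run. Thinning lowered the counts, so the number of calls depends on depth. In a simulation at 1 depth and number of libraries, 52% of 1.5-fold changes were recovered, among gene models above a minimum day 0 level.

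Each 3 against 3 comparison has 10 splits, too few for a share under 0.05, and in each the real split was the 1 with as many calls. The highest count in another split was 0 for each day against day 0, 2 for day 1 against day 0.5, 0 for day 3 against day 1 and for day 5 against day 3, and 1 for day 7 against day 5, where the real counts were 1718 to 7125 and 185, 517, 206 and 445. For the joint test, 1 of 100 groupings, the real one with 7227, was as large, the smallest share that 100 groupings allow. The highest other gave 2079, so a random labelling of the libraries is unlikely to give 7227. The other splits and groupings mix libraries of different days, which raises the spread within groups and lowers their calls. Their counts therefore do not measure how many of the real calls are false.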

Other observations

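Some early changes had turned back by day 7, a count chosen after seeing the data. Of 1341 gene models that rose at day 0.5 or day 1, 290 (21.6%) were lower at day 7 than at that time by edgeR, and 149 were then below day 0. That is 11.1% of the 1341, where 23.2% of all tested gene models were below day 0 at day 7. The median log2 change of the 290 that turned back was 0.31 at day 0.5, 0.41 at day 1 and -0.35 at day 7. Of 2308 that fell at day 0.5 or day 1, 86 (3.7%) were higher again at day 7, and 3 were then above day 0. That is 0.13% of the 2308, where 18.4% of all tested gene models were above day 0 at day 7. Gene models picked for a high or low value were compared with the same libraries again, so some return follows from the choice. The difference between the 2 shares was not tested, since gene models are not independent. The count of rises was 189 without day 0 replicate 1 and 175 without day 0 replicate 2, and the count of falls was 48, 55 and 57 without day 0 replicate 1, day 0 replicate 2 and day 1 replicate 3. With ERCC scaling, 137 rises and 24 falls had turned back.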
